A study of Zea mays with 4 samples.

How the data were processed

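RNA from maize (Zea mays) leaves at the 4-leaf stage was measured by paired-end sequencing in 2 control samples, numbered 1 and 3, and in 2 samples taken after 1 day of feeding by Spodoptera frugiperda, also numbered 1 and 3. The labels do not say whether samples of a group came from separate plants. P-values of single loci and transcripts therefore measure only the spread between these samples. Those of gene lists at a preset correlation, of neighbouring pairs and of counts of loci are taken over loci, which are not independent replicates. The protocol mentions both poly(A) selection and a poly(A)-depleted fraction, and the strand of the libraries is not stated. It also speaks of an adipose type, which a plant does not have, so which parts of it apply to these libraries is not settled; that the samples are leaves is taken from the labels.

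The submitters' processing notes name cutadapt, Bowtie2, TopHat and TopHat2 without versions. Contig and gene names point to the B73 version 4 assembly, and all coordinates are those of the deposited files. Loci whose names begin with MSTRG were assembled from the reads and merged over samples, and some join several annotated genes. The deposited gene table gives expected counts per locus, which are estimates and not tallies of reads. In 13431 loci with a single transcript, each deposited count equalled the transcript's coverage times its length divided by 75, within 1 count, in 100% of loci in every library. FPKM, which scales fragments by transcript length and library size, is the unit the authors give beside the counts in the gene table and for each transcript in the table of long non-coding RNAs (lncRNAs). The deposited lncRNA table also gives a coverage signal, the mean depth per base of a transcript, which was used here only to check how the counts were made. Coding potential scores from CPC and CNCI are deposited for predicted lncRNAs, and were not used in any test.

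Total counts per library were 78414575 in control 1, 65261381 in control 3, 60038011 in fed 1 and 64217992 in fed 3. A count of 0 was given an upper limit of 3 estimated counts. For the bounds of list members, that limit was set over the 2 libraries of a group together, and no fold is given against a group at 0. Shares of a library's counts have 95% Wilson intervals no wider than 0.0126 percentage points on either side. These intervals and limits cover counting error only, and reads without molecular identifiers are not independent molecules.

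The design was written before the data were examined and named limma on log2 FPKM, with edgeR instead if the files held counts. They did, so loci were tested with edgeR 4.0.16: filterByExpr with a minimum count of 10, TMM normalization, estimateDisp, glmQLFit and glmQLFTest, fed minus control, with Benjamini-Hochberg adjustment and a threshold of 0.05. Values are given as CPM, scaled by the TMM library size. DESeq2 1.42.0 was run on the same counts as an alternative chosen after seeing the data. lncRNA transcripts were tested with limma 3.58.1, using lmFit and eBayes with a trend on log2(FPKM + 0.1), for transcripts with a mean FPKM of at least 0.1. R 4.3.3 and Python 3.11.15 were used, with pandas 2.3.3 for tables and matplotlib 3.10.9 for plots.

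The 22 gene lists cover benzoxazinoid, jasmonate, phenylpropanoid, terpene and shikimate to tryptophan pathways, jasmonate signalling, ethylene, abscisic acid, WRKY factors, proteinase inhibitors, direct defence proteins, pathogenesis-related proteins, heat shock proteins, senescence, photosystems, the Calvin cycle with C4 enzymes, the cytosolic ribosome, and markers of mesophyll, bundle sheath, vascular, epidermal and dividing cells. They were written before the data were examined, as symbols and words of gene descriptions. The table that links symbols to the full gene names in the files was written afterwards, when some values of those genes had been displayed, because the reference table at hand shares no identifiers with this assembly. Lists were tested with limma's camera at a preset correlation of 0.01, with adjustment over the 22 lists, each of which had at least 5 tested members. Its p-values compare members with other loci at that fixed correlation, so they do not measure the spread between samples. Camera was repeated with a correlation estimated from the data, and fry was run as an alternative. Members were also adjusted over the list alone.

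Genes were named by a rule written before the data were examined: for each list the 3 members with the smallest p, and, if no locus passed the threshold, the 3 loci with the smallest p that had non-overlapping groups, a description and a mean FPKM of at least 5 in one group. For lncRNAs the rule took up to 4 transcripts in each direction that passed with non-overlapping groups. Any other gene is said to have been chosen after its values were seen. For neighbouring pairs, each tested lncRNA was matched with the nearest tested coding locus within 10 kb, and fold changes were compared by Spearman correlation with 100000 permutations.

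Alternatives covered the normalization, the filter, the pseudocount, the eBayes settings, a minimum log2 change of 1, a replicate block, and the omission of each library in turn. With a library left out, the remaining sample of its group is assumed to vary like the other group, and more loci pass the filter. The tools were tested on simulated data with 2 samples per group, 42438 loci and 200 changed loci. At each locus's own dispersion, edgeR found 5 of 67 loci changed 4-fold, 56 of 67 changed 16-fold and 62 of 66 changed 64-fold, with 18 false calls. DESeq2 found 35, 64 and 65 of them, with 188 false calls. At the trended dispersion edgeR made 9 false calls and DESeq2 62, and at 0.1 times that dispersion 4 and 3. At each locus's own dispersion, camera called 5 of 5 moved lists and 0 of 17 unmoved ones, both with the preset and with the estimated correlation. With every locus at the trended dispersion, the estimated correlation gave 0 of the 5 moved lists and the preset one gave 5. Loci were drawn independently in these simulated lists. They therefore do not show how often the preset correlation calls unmoved lists whose members are correlated. In the data the estimated correlation was 0.000228 for proteinase inhibitors but 0.439 for the cytosolic ribosome. The lncRNA test found 0 of 200 changed transcripts in simulated data, with 0 false calls, and so did the same test with trend=FALSE.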

Results

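The series set out to find coding and non-coding RNAs associated with feeding by Spodoptera frugiperda, the fall armyworm, a caterpillar that chews maize leaves. RNA was sequenced from maize leaves at the 4-leaf stage, with 2 control libraries and 2 libraries after 1 day of feeding. Total estimated counts were 78414575 in control 1, 65261381 in control 3, 60038011 in fed 1 and 64217992 in fed 3. The gene table held 53525 loci: 26862 protein-coding, 25128 assembled and unannotated, 603 annotated long intergenic non-coding and 932 of other RNA classes. Protein-coding loci took 47.9% and 47.2% of the counts in control 1 and control 3, and 54.5% and 56.3% in fed 1 and fed 3. Plastid loci took between 12.5% and 13.4% of each library, and mitochondrial loci took 2.14% of control 1, 0.892% of control 3, 1.43% of fed 1 and 1.37% of fed 3. The table of long non-coding RNAs held 14085 transcripts, of which 13331 were predicted by the authors and 754 were annotated.

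The controls differed more from each other than the fed libraries did. Across protein-coding loci, which are not independent replicates, the rank correlation of CPM was 0.893 between the controls and 0.953 between the fed libraries. Control 3 had 0 estimated counts at 4514 nuclear protein-coding loci, against 2678 in control 1, 3038 in fed 1 and 2947 in fed 3. The variation between replicates fitted by edgeR had a common coefficient of variation of 67.5%.

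The comparison of fed with control leaves asked which genes differed after 1 day of feeding. In fed leaves, gene lists for the maize toxins called benzoxazinoids, for jasmonate synthesis and signalling, and for pathogenesis-related proteins rose by camera with a preset correlation, with medians of 1.98, 1.32, 1.04 and 1.01 on the log2 scale; none of these was called with an estimated correlation. By the same test, proteinase inhibitors and genes of phenylpropanoid, terpene and ethylene pathways rose and the cytosolic ribosome list fell by 0.27, and none of them was called with an estimated correlation either. Without control 1 the ribosome list was called higher (median 0.24, camera adjusted p = 0.0424). An O-methyltransferase gene, Zm00001d038703, had 0 estimated counts in both controls and 6207 and 7089 in the fed libraries. By camera with a preset correlation, 15 of the 22 lists were called higher and 1 lower, and 6 were not called. With an estimated correlation camera called 0 lists in either direction, with 6 higher and 0 lower at an unadjusted p under 0.05 and a smallest adjusted p = 0.153 with an estimated correlation. For proteinase inhibitors, direct defence proteins and ethylene the estimated correlation was 0.000228, 0.00639 and -0.0115, below the preset 0.01. Those lists lost their call too, so a higher correlation between members does not account for the loss in them. The fit left 2 residual degrees of freedom. In simulated data the estimated correlation found 5 of 5 moved lists at each locus's own dispersion but 0 of 5 at the trended dispersion. A lost call alone therefore does not show that a list was unmoved. Fry's directional test called 0 lists as well, with 9 higher at an unadjusted p under 0.05, and its mixed test called 4. The medians did not change when members at 0 in all libraries of a group were set at their bound. This says little, since at most 6 members of a list were so set and extreme values hardly move a median.

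**Figure D1:**
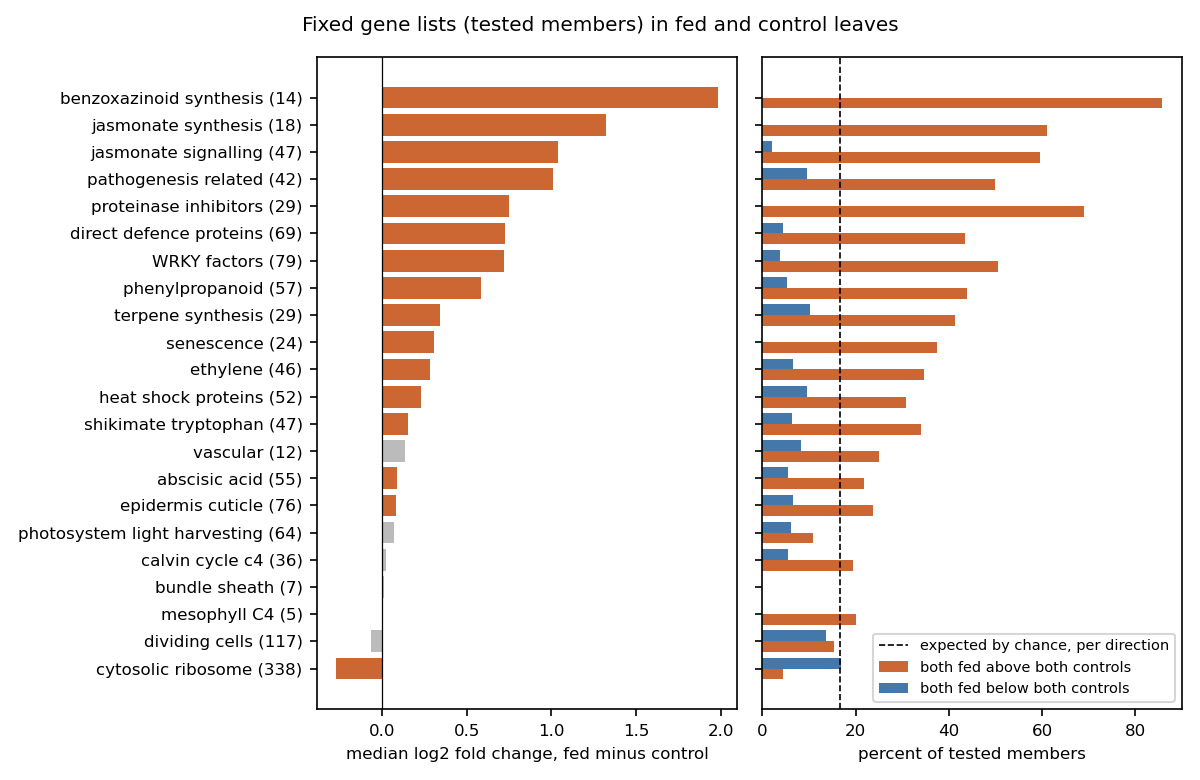
The left bars give the median log2 fold change (fed minus control) of the tested members of each of the 22 lists, in orange where camera with a preset correlation called the list and in grey where it did not. The right bars give the percent of members with both fed libraries above both controls (orange) or below them (blue), and the dashed line marks the 16.7% that chance gives per direction. Benzoxazinoid synthesis lies at 1.98 with 85.7% of members higher, and the cytosolic ribosome lies at -0.27.

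For single loci, edgeR called 0 higher and 0 lower of 42438 tested, with a smallest adjusted p of 0.146. At an unadjusted p under 0.05 there were 1518 higher and 521 lower loci, 2039 in all, where 2122 are expected by chance. DESeq2 called 561 higher and 70 lower. Of 22532 tested protein-coding loci, 1207 were higher and 172 lower at an unadjusted p under 0.05, and DESeq2 called 483 higher and 20 lower. Both fed libraries lay above both controls at 20.2% of these loci and below them at 13.7%, where chance gives 16.7% per direction. Assembled and unannotated loci went the other way, at 13.1% and 19.2%, and all tested loci stood at 16.9% and 16.3%. The edgeR counts were 925 higher and 55 lower without control 1 and 242 higher and 63 lower without control 3, but 0 and 0 without fed 1 or without fed 3. At those last omissions 2010 and 1344 loci had an unadjusted p under 0.05. Without control 1, control 3 was the only control. At the 361 protein-coding loci far lower in control 3 than elsewhere, given below, a rise without control 1 can come from control 3 alone. In simulated data DESeq2 made 188 false calls at each locus's own dispersion, 62 at the trended dispersion and 3 at a far smaller dispersion, against 18, 9 and 4 by edgeR.

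Among loci with a description, non-overlapping groups and a mean FPKM of at least 5 in 1 group, 3 were taken by smallest p. None of these 3 passed in edgeR. Zm00001d038703, annotated as O-methyltransferase ZRP4 on chromosome 6 from 162999184 to 163000694, was at 99.1 ± 3.10 CPM (SD, n = 2) in fed leaves and at 0 in both controls (adjusted p = 0.146). Glutathione transferase25, Zm00001d048558 on chromosome 9 from 158667068 to 158667751, was at 0.0888 ± 0.0331 CPM in controls and 18.5 ± 3.13 CPM in fed leaves. It encodes an enzyme that joins glutathione to toxic compounds, and its log2 fold change was 7.66 with an SE of 0.47 (adjusted p = 0.146). A locus joining Zm00001d049110 and Zm00001d049111 on chromosome 4, from 16374299 to 16423699, is annotated as cysteine proteinase inhibitor 5. Its level was 0.683 ± 0.225 CPM in controls and 19.7 ± 0.284 CPM in fed leaves (adjusted p = 0.236). The first 2 of these loci passed with limma on log2(FPKM + 1), each with an adjusted p of 0.0433, and the inhibitor locus did not, at 0.0566.

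**Figure D2:**
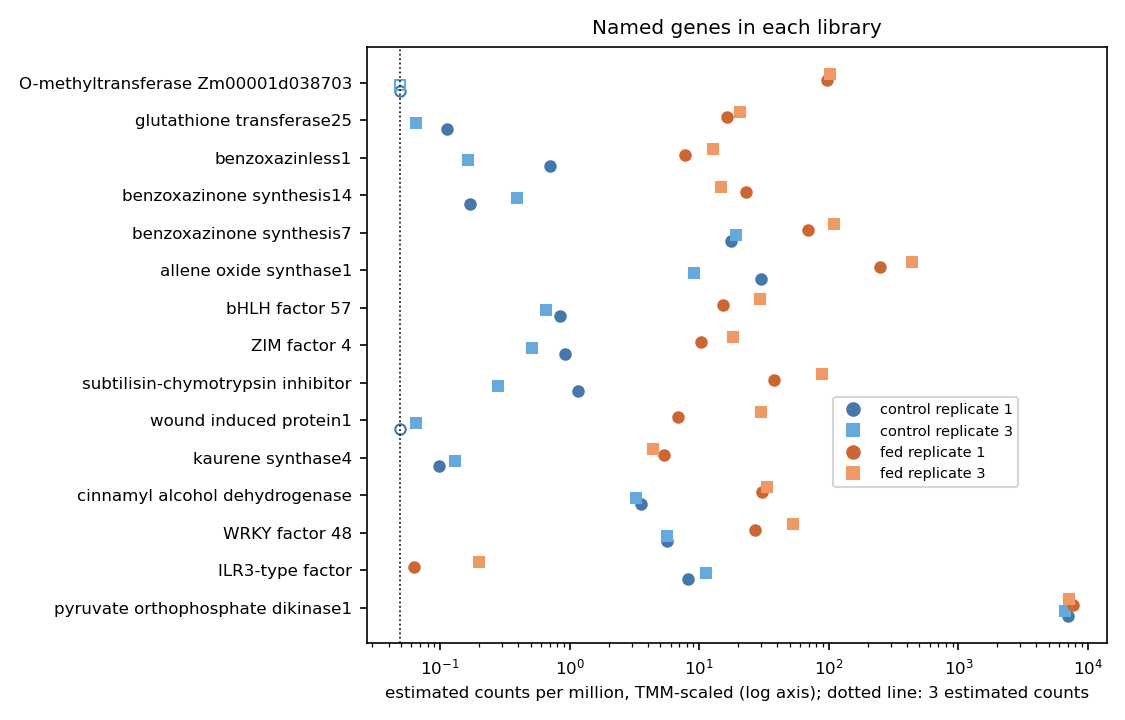
Each symbol is the level of 1 gene in 1 library, in CPM on a log axis, for 15 genes in the 2 control and 2 fed libraries. Open symbols on the dotted line, which marks 3 estimated counts, stand for a count of 0. Zm00001d038703 was at 0 in both controls and at 96.9 and 101 CPM in fed 1 and fed 3.

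Benzoxazinoids are indole-derived toxins that grasses hold in their leaves against chewing insects. The 14 tested members of this list rose by a median of 1.98 (camera adjusted p = 4.17e-21; adjusted p = 0.153 with an estimated correlation). Both fed libraries lay above both controls for 12 members and below for 0, and 9 members passed when adjusted over the list alone. None of the 14 passed over all loci in edgeR, with 10 at an unadjusted p under 0.05, and DESeq2 called 4. Benzoxazinless1, the first committed enzyme of the pathway (Zm00001d048709, chromosome 4 from 3833330 to 3835353), was at 0.432 ± 0.380 CPM in controls and 10.3 ± 3.63 CPM in fed leaves. Benzoxazinone synthesis14 (Zm00001d004921, chromosome 2 from 148710174 to 148711618), which acts late in the pathway, was at 0.280 ± 0.159 CPM and 19.0 ± 5.87 CPM. The O-methyltransferase benzoxazinone synthesis7 (Zm00001d049179, chromosome 4 from 19409404 to 19410924) was at 18.3 ± 1.17 CPM and 89.7 ± 29.2 CPM. The related methyltransferase genes benzoxazinone synthesis12 and the joined locus of benzoxazinone synthesis10 and 11, chosen after their values were seen, had 54 and 29 estimated counts in control 1 and 0 in control 3. Their counts were 3524 and 2199 in fed 1 and 11320 and 4978 in fed 3, and reads of such near-identical copies cannot be placed with certainty. The members that did not separate the groups were beta glucosidase1 and beta-glucosidase2, enzymes that release the toxin from its glucoside, with log2 fold changes of -0.59 and -0.05.

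Jasmonate is the hormone that plants make when leaves are wounded. The 18 tested genes of its synthesis rose by a median of 1.32 (camera adjusted p = 4.11e-15; adjusted p = 0.181 with an estimated correlation), and 7 of them passed when adjusted over the list alone. Both fed libraries were above both controls for 11 and below for 0. Allene oxide synthase1 (Zm00001d048021, chromosome 9 from 148185906 to 148187354), which commits fatty acid peroxides to jasmonate, was at 19.5 ± 14.6 CPM in controls and 344 ± 137 CPM in fed leaves. A second allene oxide synthase, Zm00001d013185 on chromosome 5 from 6100495 to 6102030, was at 4.22 ± 2.54 CPM and 34.1 ± 11.6 CPM. Lipoxygenase9 (Zm00001d027893, chromosome 1 from 16948608 to 16955122) was at 5.98 ± 0.382 CPM and 15.98 ± 0.445 CPM. Lipoxygenase10, chosen after its values were seen as the most abundant member, was at 2380 ± 615 CPM and 5568 ± 168 CPM. The 47 tested genes of jasmonate signalling rose by a median of 1.04 (camera adjusted p = 1.01e-20; adjusted p = 0.179 with an estimated correlation). Of these, 28 had both fed libraries above both controls and 1 had them below, and 13 passed when adjusted over the list alone. Among them were ZIM-transcription factor 4 (Zm00001d048263, chromosome 9 from 153418013 to 153418531) and ZIM-transcription factor 18 (Zm00001d033050, chromosome 1 from 248529926 to 248530474), of the family of JAZ repressors that jasmonate removes. ZIM-transcription factor 4 was at 0.709 ± 0.286 CPM in controls and 14.2 ± 5.52 CPM in fed leaves, and ZIM-transcription factor 18 was at 0.0351 ± 0.0496 CPM and 6.83 ± 2.65 CPM. BHLH-transcription factor 57 (Zm00001d043706, chromosome 3 from 207941097 to 207942500) was at 0.748 ± 0.132 CPM and 22.1 ± 9.93 CPM. No member of either list passed over all loci in edgeR, with 8 and 19 at an unadjusted p under 0.05, and DESeq2 called 7 and 10. Without fed 3 the signalling median was 0.59 and the list was still called.

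Proteinase inhibitors block digestive enzymes in the insect gut. The 29 tested members rose by a median of 0.75 (camera adjusted p = 6.02e-20; adjusted p = 0.153 with an estimated correlation). Both fed libraries were above both controls for 20 and below for 0, and 7 passed when adjusted over the list alone. A subtilisin-chymotrypsin inhibitor, Zm00001d011079 on chromosome 8 from 138332949 to 138333170, was at 0.721 ± 0.627 CPM in controls and 63.1 ± 36.2 CPM in fed leaves. Wound induced protein1 (Zm00001d008548, chromosome 8 from 12671727 to 12672398), a Bowman-Birk inhibitor, had 0 and 4 estimated counts in the controls and 437 and 2081 in the fed libraries. The 69 direct defence proteins, such as chitinases and lectins, rose by a median of 0.73 (camera adjusted p = 7.30e-12; adjusted p = 0.153 with an estimated correlation). Of these, 30 were higher in both fed libraries and 3 lower, and 4 passed when adjusted over the list alone. Chitinase A1 (Zm00001d003190, chromosome 2 from 35066062 to 35067313) was at 6.99 ± 6.82 CPM in fed leaves and at 0 in both controls. Basic endochitinase B (Zm00001d036366, chromosome 6 from 85857785 to 85858714) was at 1.68 ± 0.665 CPM in fed leaves and at 0 in controls. An acidic endochitinase, Zm00001d048903 on chromosome 4 from 7429245 to 7430150, had 0 and 2 estimated counts in the controls and 107 and 308 in the fed libraries. The 42 pathogenesis-related genes rose by a median of 1.01 (camera adjusted p = 1.64e-11; adjusted p = 0.179 with an estimated correlation), with 21 higher and 4 lower in both fed libraries and 4 that passed when adjusted over the list alone. Glucan endo-1,3-beta-glucosidase homolog1 (Zm00001d042143, chromosome 3 from 153385868 to 153387244), an enzyme that cuts fungal wall glucans, was at 0.175 ± 0.169 CPM and 10.3 ± 7.71 CPM. An osmotin-like protein, Zm00001d041553 on chromosome 3 from 126926038 to 126926802, had 5 and 0 counts in the controls and 453 and 228 in the fed libraries. A thaumatin-family gene, Zm00001d030304 on chromosome 1 from 121172256 to 121174236, had 0 and 4 counts and then 409 and 146. Over all loci 0 members of these 3 lists passed in edgeR, with 11, 16 and 12 higher and 0, 0 and 1 lower at an unadjusted p under 0.05, and DESeq2 called 7, 8 and 8. Without control 1 the 3 medians were 1.45, 1.42 and 3.22, the inhibitor median was 1.13 without control 3 and 1.22 without fed 3, and each call was kept.

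WRKY proteins are plant transcription factors of stress and defence. The 79 tested members rose by a median of 0.72 (camera adjusted p = 1.30e-14; adjusted p = 0.227 with an estimated correlation). Of these, 40 were higher in both fed libraries and 3 lower, 10 passed when adjusted over the list alone and DESeq2 called 11. Over all loci edgeR called 0, with 18 higher and 1 lower at an unadjusted p under 0.05. WRKY-transcription factor 48 (Zm00001d015515, chromosome 5 from 95183890 to 95185688) was at 5.63 ± 0.0294 CPM in controls and 39.7 ± 18.2 CPM in fed leaves. WRKY-transcription factor 124 (Zm00001d046805, chromosome 9 from 106603130 to 106604806) was at 5.24 ± 1.82 CPM in fed leaves and at 0 in both controls. WRKY-transcription factor 114 (Zm00001d036726, chromosome 6 from 99175591 to 99177057) was at 6.93 ± 6.45 CPM in fed leaves and at 0 in both controls.

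Phenylpropanoids include lignin, which stiffens cell walls. The 57 tested genes of this pathway rose by a median of 0.59 (camera adjusted p = 6.82e-13; adjusted p = 0.227 with an estimated correlation), with 25 higher and 3 lower in both fed libraries and 5 that passed when adjusted over the list alone. Zm00001d004443, a probable cinnamyl alcohol dehydrogenase on chromosome 2 from 112231521 to 112233025, was at 3.38 ± 0.199 CPM in controls and 32.05 ± 1.87 CPM in fed leaves. Phenylalanine ammonia lyase4, the entry enzyme of the pathway (Zm00001d051166, chromosome 4 from 146846109 to 146848259), was at 0.231 ± 0.0496 CPM and 2.77 ± 0.819 CPM. Hydroxycinnamoyltransferase2 (Zm00001d027948, chromosome 1 from 18147157 to 18148937) was at 2.95 ± 0.723 CPM in fed leaves and at 0 in both controls. The 47 genes of the shikimate to tryptophan pathway, which feeds both phenylpropanoids and benzoxazinoids, rose by a median of 0.15 (camera adjusted p = 6.74e-05; adjusted p = 0.397 with an estimated correlation). Of these, 16 were higher and 3 lower in both fed libraries, and 2 passed when adjusted over the list alone. A locus joining Zm00001d034453 and Zm00001d034461, annotated as tryptophan synthase alpha chain on chromosome 1 from 293423687 to 293624784, was at 4.78 ± 1.69 CPM and 98.6 ± 79.95 CPM. Arogenate dehydratase6 (Zm00001d003830, chromosome 2 from 61203599 to 61204879), which makes phenylalanine, was at 9.34 ± 0.386 CPM and 87.7 ± 62.5 CPM. Anthranilate synthase alpha subunit 2 (Zm00001d028536, chromosome 1 from 38520831 to 38526523) was at 24.8 ± 1.14 CPM and 69.9 ± 14.1 CPM. No member of the 2 lists passed over all loci in edgeR, with 13 and 7 at an unadjusted p under 0.05, and DESeq2 called 7 and 6. Without control 1 the medians were 2.07 and 0.55. The shikimate list lost its call without control 3 (median 0.07, camera adjusted p = 0.171) and without fed 3 (0.07, 0.0725), and its median was 0.30 without fed 1.

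Terpenes are volatile or antimicrobial compounds of attacked leaves. The 29 tested genes rose by a median of 0.34 (camera adjusted p = 3.09e-10; adjusted p = 0.252 with an estimated correlation), with 12 higher and 3 lower in both fed libraries. Of these, 5 passed when adjusted over the list alone and DESeq2 called 6, while edgeR called 0 over all loci, with 6 at an unadjusted p under 0.05. Deoxy xylulose synthase 2, an enzyme that starts plastid terpene synthesis (Zm00001d019060, chromosome 7 from 14494700 to 14497925), was at 4.06 ± 0.168 CPM in controls and 178 ± 144 CPM in fed leaves. Geranylgeranyl pyrophosphate synthase3 (Zm00001d008370, chromosome 8 from 6617307 to 6618398) was at 0.827 ± 0.218 CPM and 33.1 ± 22.4 CPM. Kaurene synthase4 (Zm00001d041082, chromosome 3 from 96077271 to 96081198) was at 0.115 ± 0.0231 CPM and 4.86 ± 0.642 CPM. An unannotated locus that the files name terpene synthase10, on chromosome 10 from 73708880 to 73712646, was chosen after its values were seen. It had 0 estimated counts in both controls, 965 in fed 1 and 4227 in fed 3. The list was not called without control 3 (median 0.08, camera adjusted p = 0.214), and its median was 2.24 without control 1.

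Ethylene is a gaseous hormone of wounding and ripening. Its 46 tested genes rose by a median of 0.28 (camera adjusted p = 2.46e-06; adjusted p = 0.153 with an estimated correlation), with 16 higher and 3 lower in both fed libraries, and 2 that passed when adjusted over the list alone. Over all loci edgeR called 0 of them, with 7 at an unadjusted p under 0.05, and DESeq2 called 4. The smallest p belonged to 3 loci for the enzyme that makes ethylene, 1-aminocyclopropane-1-carboxylate oxidase, on chromosome 10. The joined locus of 1-aminocyclopropane-1-carboxylate oxidase4 and 3 (90634003 to 90657509) had 2 and 3 counts in the controls and 2241 and 523 in the fed libraries. Zm00001d024850, 1-aminocyclopropane-1-carboxylate oxidase 5 (90614501 to 90615758), had 0 and 0 and then 186 and 84 counts. 1-aminocyclopropane-1-carboxylate oxidase15 (Zm00001d024843, 90456450 to 90457394) was at 8.43 ± 4.001 CPM in controls and 34.1 ± 1.83 CPM in fed leaves. Without control 3 the median was 0.50 and the list was still called.

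Lists for abscisic acid, senescence, heat shock proteins and the leaf surface were called higher with small medians. Abscisic acid, a hormone of drought, had 55 tested genes with a median of 0.09 (camera adjusted p = 0.0396; adjusted p = 0.227 with an estimated correlation). Its key enzyme genes nine-cis-epoxycarotenoid dioxygenase5 (Zm00001d018819, chromosome 7 from 6342456 to 6344361) and viviparous14 (Zm00001d033222, chromosome 1 from 255021507 to 255023321) were at 6.32 ± 5.89 CPM and 12.2 ± 10.8 CPM in fed leaves. The first was at 0 in both controls and the second was at 0.896 ± 0.236 CPM. Dehydrin3 (Zm00001d051420, chromosome 4 from 157872166 to 157873662) was at 0 in controls and 2.27 ± 2.35 CPM in fed leaves. The 24 senescence genes had a median of 0.31 (camera adjusted p = 0.00921; adjusted p = 0.227 with an estimated correlation). STAY-GREEN 1 (Zm00001d006211, chromosome 2 from 201912795 to 201914678), which starts chlorophyll breakdown, was at 0.776 ± 0.172 CPM and 19.0 ± 20.3 CPM. Senescence associated gene 20 (Zm00001d022569, chromosome 7 from 180129805 to 180131184) was at 16.6 ± 10.9 and 58.6 ± 18.4 CPM, and pheophytinase (Zm00001d015205, chromosome 5 from 79250420 to 79260637) was at 47.3 ± 2.94 and 96.8 ± 24.9 CPM. The 52 heat shock genes had a median of 0.23 (camera adjusted p = 0.0246; adjusted p = 0.477 with an estimated correlation). Heat-shock protein 101 (Zm00001d038806, chromosome 6 from 164808309 to 164812048) had 4 and 0 counts in the controls and 130 and 444 in the fed libraries, and heat shock protein22 (Zm00001d052194, chromosome 4 from 182772609 to 182773786) had 0 and 0 and then 91 and 33. Heat shock 70 kDa protein 14 (Zm00001d009948, chromosome 8 from 91813684 to 91819885) was at 18.7 ± 1.97 and 9.005 ± 2.67 CPM. The 76 genes of epidermis and cuticle had a median of 0.08 (camera adjusted p = 0.00346; adjusted p = 0.477 with an estimated correlation). Its members with the smallest p were 2 lipase-like genes and the wax enzyme gene Zm00001d027766 (3-ketoacyl-CoA synthase 2, chromosome 1 from 13137072 to 13140293), which was at 0.0608 ± 0.00660 and 1.21 ± 1.25 CPM. The lipase-like genes were Zm00001d014820 (chromosome 5 from 64545559 to 64547354), at 0.753 ± 0.231 and 4.39 ± 0.548 CPM, and Zm00001d040733 (chromosome 3 from 60679832 to 60682468), at 7.55 ± 0.260 and 14.9 ± 1.99 CPM. Adjusted over the list alone, 0 members of these 4 lists passed in edgeR, with 6, 3, 4 and 7 higher and 0, 0, 1 and 1 lower at an unadjusted p under 0.05, and DESeq2 called 3, 1, 2 and 1.

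Each of these 4 calls depended on single libraries. Some also depended on the loci tested. With coding loci alone, abscisic acid and heat shock (camera adjusted p = 0.244 each) and senescence (0.0719) were not called, while epidermis and cuticle was (0.047). The abscisic acid call was lost without control 3 (median 0.10, camera adjusted p = 0.541) and without fed 3 (0.07, 0.124), and its median was 0.68 without control 1 and 0.15 without fed 1. Senescence lost its call without control 1 (0.20, 0.228), and its median was 0.46 without control 3. Heat shock lost its call without control 1 (0.27, 0.415) and turned negative without fed 3 (-0.09, 0.451), with medians of 0.52 without control 3 and 0.46 without fed 1. Epidermis and cuticle turned to -0.04 without control 3 (camera adjusted p = 0.171) and lost its call without fed 3 (0.02, 0.0725). That list stood at 1.64 without control 1 and 0.03 without fed 1.

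The 338 tested genes of the cytosolic ribosome fell by a median of 0.27 (camera adjusted p = 0.00239; adjusted p = 0.778 with an estimated correlation), with 15 higher and 57 lower in both fed libraries. Zm00001d021480, ribosomal protein S4-3 on chromosome 7 from 153348678 to 153355461, was at 38.1 ± 4.76 CPM in controls and 18.9 ± 0.674 CPM in fed leaves. Zm00001d043097, an L34e-family gene on chromosome 3 from 189160211 to 189160861, was at 3.56 ± 0.398 and 7.19 ± 0.721 CPM. Zm00001d022434, annotated as ribosomal protein S6 kinase on chromosome 7 from 177646176 to 177649846 and so not part of the ribosome, was at 5.25 ± 2.38 and 12.4 ± 0.701 CPM. In edgeR 0 members passed, over the list alone or over all loci, with 2 higher and 3 lower at an unadjusted p under 0.05, and DESeq2 called 0. The median was 0.24 and the list was called higher without control 1 (camera adjusted p = 0.0424), it was -0.59 without control 3, and the call was lost without fed 1 (median -0.09, camera adjusted p = 0.533). Control 1 stood above the mean of the 4 libraries by a median of 0.37 for this list, control 3 stood at -0.21, fed 1 at -0.17 and fed 3 at 0.01.

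Photosynthesis genes and the markers of mesophyll, bundle sheath, vascular and dividing cells showed no called difference over all libraries. The 64 photosystem and light-harvesting genes had a median of 0.07 and a mean of -0.02, and the test pointed down (camera adjusted p = 0.991). This list was called higher without control 1 (median 0.25, camera adjusted p = 0.01003) and lower without control 3 (-0.13, 0.0344). The 36 genes of the Calvin cycle and the C4 pathway had a median of 0.03 (camera adjusted p = 0.268). Phosphoenolpyruvate carboxylase1, the first enzyme of C4 carbon fixation (Zm00001d046170, chromosome 9 from 68851094 to 68856482), was at 8096 ± 1457 CPM in controls and 7035 ± 115 CPM in fed leaves. Pyruvate, orthophosphate dikinase1 (Zm00001d038163, chromosome 6 from 150024241 to 150035717) was at 6847 ± 248 and 7434 ± 389 CPM. The 5 mesophyll markers had a median of 0.00 and a mean of -0.06, with the test pointing down (camera adjusted p = 0.919). For the 7 bundle sheath markers the median was 0.02, the mean was -0.02 and the test pointed down (camera adjusted p = 0.991). RUBISCO activase2 (Zm00001d048593, chromosome 4 from 921608 to 923738) was at 1547 ± 544 and 1450 ± 177 CPM. The 12 vascular markers had a median of 0.14 (camera adjusted p = 0.513) and the 117 genes of dividing cells one of -0.06 (camera adjusted p = 0.815). Minichromosome maintenance7, of the DNA replication helicase (Zm00001d049190, chromosome 4 from 19769075 to 19776143), was at 8.21 ± 0.378 CPM in controls and 3.22 ± 0.0855 CPM in fed leaves. The histone H3.2 genes Zm00001d012276 (chromosome 8 from 171739920 to 171740516) and Zm00001d003730 (chromosome 2 from 56683255 to 56683907) lay the other way, at 0.224 ± 0.0397 and 0.972 ± 0.161 CPM and at 0.0491 ± 0.0694 and 0.850 ± 0.0312 CPM. With an estimated correlation the adjusted p of these 6 lists lay between 0.44 and 0.998. Among other members with the smallest p were sucrose transporter7, which loads sugar into the phloem (28.04 ± 0.599 and 49.5 ± 16.04 CPM), and sucrose synthase1 (87.2 ± 23.3 and 53.45 ± 5.04 CPM). Light harvesting chlorophyll a/b binding protein5 was at 749 ± 531 and 448 ± 6.09 CPM, dicarboxylic acid transporter1 at 38.3 ± 24.6 and 32.9 ± 4.37 CPM, and RUBISCO activase3 at 25.3 ± 15.9 and 29.6 ± 12.9 CPM. Dicarboxylic acid transporter2 was at 354 ± 77.4 and 296 ± 68.0 CPM, phloem protein gene Zm00001d030181 at 2.42 ± 0.262 and 3.76 ± 1.01 CPM, and phosphoenolpyruvate carboxylase kinase1 at 0.974 ± 0.151 and 3.05 ± 1.59 CPM. The light-harvesting gene Zm00001d001857 was at 126 ± 86.8 and 60.7 ± 5.92 CPM, the oxygen-evolving enhancer gene Zm00001d002993 at 12.3 ± 0.457 and 9.37 ± 0.595 CPM, and the alpha carbonic anhydrase gene Zm00001d046784 at 0.0327 ± 0.0463 and 0.608 ± 0.374 CPM. In edgeR 0 members of these 6 lists passed over the list alone, with 4 higher and 1 lower at an unadjusted p under 0.05, and DESeq2 called 1. That 1 was a carbonic anhydrase, Zm00001d031778 on chromosome 1 from 201515268 to 201517431, with 0 counts in both controls and 52 and 700 in the fed libraries.

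**Figure D3:**
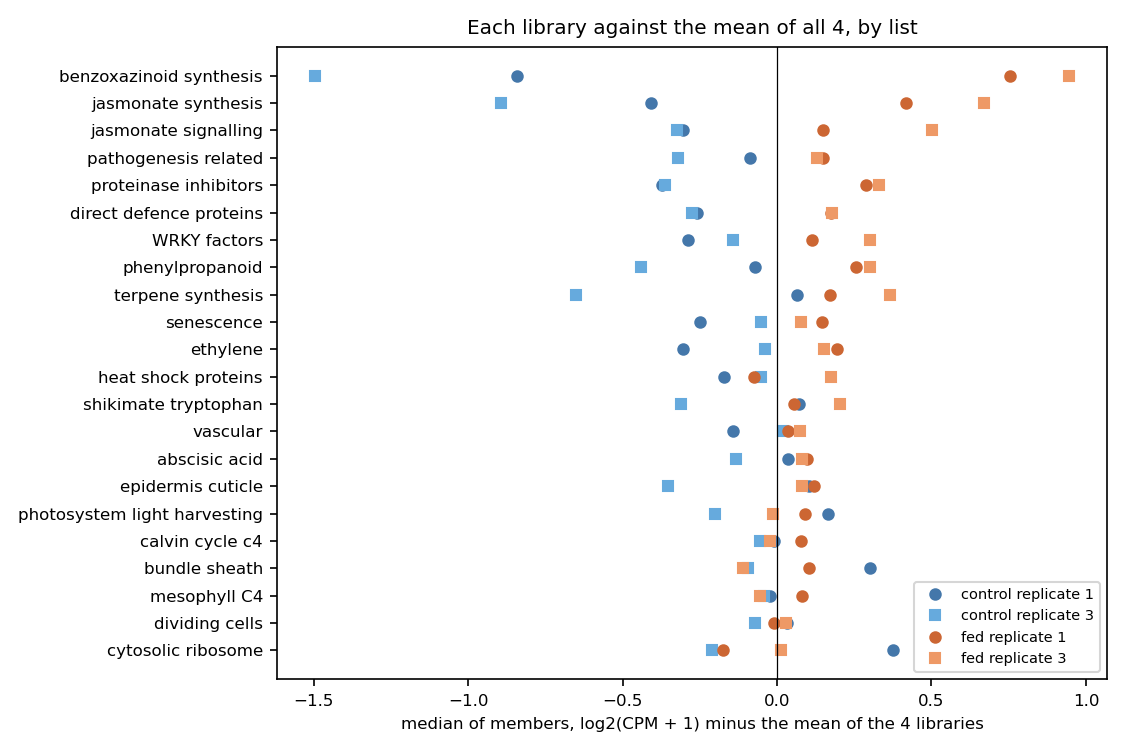
Each symbol is the median over a list's tested members of 1 library's log2(CPM + 1) relative to the mean of the 4 libraries. For benzoxazinoid synthesis the controls lie at -0.84 and -1.49 and the fed libraries at 0.75 and 0.95, while for the cytosolic ribosome control 1 lies at 0.37 and the other libraries between -0.21 and 0.01.

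Outside the lists, the loci given here were chosen after their values were seen, and none of them passed in edgeR. Zm00001d027911, annotated as the transcription factor ILR3 on chromosome 1 from 17368177 to 17370245, was at 9.76 ± 2.26 CPM in controls and 0.131 ± 0.0973 CPM in fed leaves (adjusted p = 0.268). A protein kinase gene, Zm00001d006844 on chromosome 2 from 217764077 to 217767438, was at 20.8 ± 0.722 and 3.69 ± 0.674 CPM (adjusted p = 0.276). UDP-glucosyl transferase1 (Zm00001d037383, chromosome 6 from 123804940 to 123806574) was at 18.0 ± 0.470 and 8.39 ± 1.70 CPM (adjusted p = 0.713). Among those with higher values, a locus of joined patatin-like lipase genes on chromosome 2, from 236348383 to 236372548, was at 0.255 ± 0.175 and 54.4 ± 14.5 CPM (adjusted p = 0.260). An amino acid transporter gene, Zm00001d044387 on chromosome 3 from 226714841 to 226734363, was at 0 in controls and 20.7 ± 10.7 CPM in fed leaves (adjusted p = 0.261).

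The comparison of lncRNAs asked which non-coding transcripts differed after feeding. A transcript antisense to lipoxygenase1, MSTRG.19689.1 on chromosome 3 from 171278655 to 171422967, was listed at 0 in both controls and at 51.4 and 18.9 FPKM in fed 1 and fed 3. The lipoxygenase genes under it together had 7177 and 105 estimated counts in control 1 and control 3. In fed 1 and fed 3 these genes had 162261 and 73353. Intergenic transcripts MSTRG.28536.1 (chromosome 5 from 73177352 to 73177640) and MSTRG.14274.1 (chromosome 2 from 162547968 to 162548178) were listed at 0 in both controls too. MSTRG.28536.1 was at 12.8 and 11.7 FPKM in the fed libraries, and MSTRG.14274.1 was at 8.62 and 5.95 FPKM. The annotated lncRNA Zm00001d001491_T001 (chromosome 6 from 173351422 to 173351735) was at 0.116 and 0.1002 FPKM in controls and 17.4 and 15.7 FPKM in fed leaves. In limma these 4 lncRNAs rose, with adjusted p of 3.74e-27, 9.20e-11, 2.06e-05 and 3.09e-16, each with both fed libraries above both controls. The whole locus of the last had 1512 and 1520 estimated counts in controls and, at lower values, 1328 and 959 in fed leaves. MSTRG.29983.2, antisense to Zm00001d016569 on chromosome 5 from 167820308 to 167822797, fell from 49.4 and 2.33 FPKM to 1.18 and 0.537 FPKM (adjusted p = 1.27e-07). MSTRG.10221.1, at a locus named for a group II intron (chromosome 10 from 129701608 to 129706226) fell from 261 and 21.7 to 13.8 and 16.5 FPKM (adjusted p = 0.000621), and the annotated Zm00001d022877_T001 (chromosome 1 from 186700285 to 186700520) fell from 8.18 and 8.34 to 0.530 and 4.72 FPKM (adjusted p = 0.00965).

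**Figure D4:**
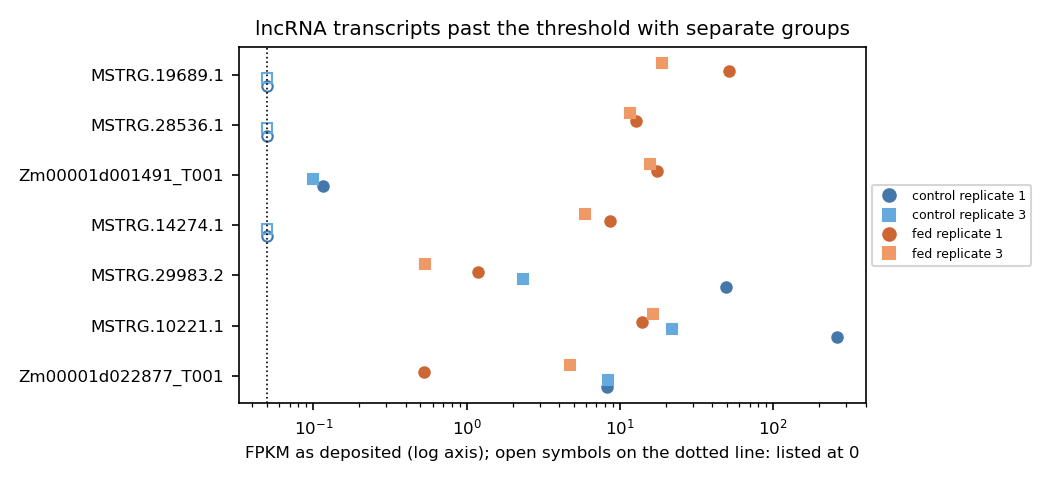
Each symbol is the FPKM of 1 of the 7 named lncRNA transcripts in 1 library, on a log axis, for the 2 control and 2 fed libraries. Open symbols mark transcripts listed at 0, and MSTRG.19689.1 was listed at 0 in both controls and at 51.4 and 18.9 FPKM in the fed libraries.

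Of 13732 lncRNA transcripts tested in limma, 14 were called higher and 11 lower, with 415 at an unadjusted p under 0.05, where 687 are expected by chance. Both fed libraries lay above both controls for 10 of the 14 and below for 3 of the 11, and among all tested transcripts for 13.6% and 15.7%, where chance gives 16.7% per direction. Of the 25 called transcripts, 6 were seen in 1 library alone, and 5 belonged to the locus MSTRG.17681. In this fit every transcript took its spread from the trend, with none of its own. With a single prior spread limma called 0 higher and 0 lower, and it also called 0 and 0 without control 1, without control 3, without fed 1 and without fed 3. On the estimated counts of 9530 lncRNA loci edgeR called 0 in either direction, with 340 at an unadjusted p under 0.05, and DESeq2 called 28 higher and 16 lower.

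The last comparison asked whether lncRNAs and neighbouring genes moved together. Across 5322 pairs of a lncRNA and the nearest coding locus within 10 kb, the fold changes had a Spearman rho of 0.07 (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). Pairs of loci are not independent replicates, and 7 such relations were computed. When lncRNA fold changes came from replicates 1 and gene fold changes from replicates 3, so that they shared no library, rho was 0.03 (permutation p = 0.0152). With the replicates exchanged, rho was 0.00497 (permutation p = 0.715).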

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

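Results were recomputed with 1 choice changed at a time, with some exceptions. The limma fits of genes changed the tool, the unit (FPKM), the scaling, the filter (23286 loci against 42438) and the pseudocount together. DESeq2 on genes changed the scaling, the fitted spread, the test and the filter together, with an adjusted p for 40036 loci. The tests of lncRNA loci changed the feature (9530 loci against 13732 transcripts), the unit, the tool and the filter. limma on log2(FPKM + 1), DESeq2, coding loci alone, the tests of lncRNA loci, the limit to non-overlapping transcripts and the overlapping and second replicate-swapped pairs were chosen after seeing the data. edgeR called 0 loci higher and 0 lower, with 2039 at an unadjusted p under 0.05, and 0 again with a higher filter, other size factors, a replicate block, robust fitting, coding loci alone and a minimum change. It called 134 higher and 11 lower with no filter, limma on log2(FPKM + 0.1) called 1 higher and limma on log2(FPKM + 1) called 7, DESeq2 called 561 and 70, and leaving out 1 library gave 0 to 925 higher and 0 to 63 lower. The replicate block gave 15 lists higher and 1 lower, as before. Lists called higher numbered 11 to 15 over the alternatives, except 0 higher and 0 lower by camera with an estimated correlation (6 and 0 at an unadjusted p under 0.05) and by fry's directional test (9 and 0). Leaving out library omissions, medians of called lists ran from 0.29 to 1.60 for pathogenesis-related proteins, 0.75 to 2.54 for proteinase inhibitors, 0.61 to 1.11 for jasmonate signalling, 0.24 to 0.55 for terpenes, 0.11 to 0.42 for ethylene, 0.14 to 0.41 for shikimate to tryptophan, 0.08 to 0.38 for abscisic acid, 0.07 to 0.41 for senescence, -0.01 to 0.37 for heat shock, 0.02 to 0.49 for epidermis and cuticle, and -0.32 to -0.04 for the cytosolic ribosome. Lists called lower numbered 0 to 2 with 1 library left out. The causes were not tested. Abscisic acid and heat shock were not called with a filter 5 times as high, in the limma variants or with coding loci alone, and senescence was not called in quantile normalized limma (adjusted p = 0.095) or with coding loci alone (0.0719), in a range of 0.00101 to 0.228 over its alternatives.

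Bundle sheath markers had a median of 0.044 with no filter, 0.10 with the replicate block, 0.24 in limma on log2(FPKM + 0.1), 0.00705 after quantile normalization, 0.19 in limma on log2(FPKM + 1) with a trend or trend=FALSE, 0.0154 in the fit used for fry, and -0.28 to 0.0646 with 1 library left out. Photosystem genes had 0.10 with no filter, 0.0849 with median-of-ratios factors, 0.25 in limma on log2(FPKM + 0.1), 0.10 after quantile normalization, 0.24 in limma on log2(FPKM + 1) with or without a trend, 0.072 in the fit used for fry, and -0.13 to 0.25 with 1 library left out. For dividing cells the values were 0.23, 0.0112 and 0.19 in limma on log2(FPKM + 0.1), on quantile normalized values and on log2(FPKM + 1), and -0.10 to 0.10 with 1 library left out, and for mesophyll markers 0.14, 0.0224, 0.14 and -0.0927 to 0.0597. None of these 4 lists was called before. With 1 library left out the cytosolic ribosome ran from -0.59 to 0.24, epidermis and cuticle from -0.0402 to 1.64, and heat shock from -0.09 to 0.52. RUBISCO activase2 changed sign to 0.0851 in limma on log2(FPKM + 0.1) and to 0.0849 in limma on log2(FPKM + 1), with or without a trend, and ran from -0.41 to 0.31 with 1 library left out. In the same limma fits dicarboxylic acid transporter1 had 0.0751 and 0.0565, and over the omissions -0.77 to 0.65, and with 1 library left out RUBISCO activase3 ran from -0.30 to 1.07 and light harvesting chlorophyll a/b binding protein5 from -1.34 to 0.26. The causes were not tested. Of the other values of named genes, 959 kept their direction and their side of the threshold and 172 came to pass it.

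lncRNA calls, 14 higher and 11 lower, were 17 and 7 with a pseudocount of 1, 6 and 0 with no filter, 4 and 0 with a filter 5 times as high, 7 and 1 with robust=TRUE, 0 and 0 with trend=FALSE, 0 and 0 without any 1 of the 4 libraries, 15 and 11 with the replicate block, and 10 and 3 among non-overlapping transcripts. On locus counts edgeR gave 0 and 0, with 340 at an unadjusted p under 0.05, and DESeq2 gave 28 and 16. The neighbour correlation lay between 0.03 and 0.08 in the other alternatives but was 0.00497 with lncRNAs from replicates 3 and genes from replicates 1. The causes were not tested. A count of 0 leaves a locus at up to 3 estimated counts, so no fold is given against controls at 0.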

Other observations

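Tests in this part were chosen after the result was seen, except the fit of lncRNAs with trend=FALSE, which was planned. No biological explanation of the patterns below was tested other than those named.

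Among groups formed from deposited gene annotation, camera called 77 terms higher and 34 lower of 1192 terms with 10 to 300 genes, and the smallest adjusted p = 0.921 with an estimated correlation. Response to wounding had a median log2 fold change of 1.36 over 62 genes, with 40 higher and 2 lower in both fed libraries, where chance gives 16.7% per direction. Chitinase activity had 2.43 over 18 genes, or 1.70 without control 3, and 4 of its 10 genes with at least 50 estimated counts in each other library are among the loci low in control 3 given below (odds ratio 29.8, adjusted p = 0.00372). The median was 0.52 over 42 genes for glutathione transferase activity (camera adjusted p = 1.09e-05), or 0.93 without control 1. Water channel activity had 0.89 over 18 genes (camera adjusted p = 0.00048), and it was not called without control 1 (0.125) and had a median of 0.46 without fed 3. The lower terms included aminoacyl-tRNA ligase activity, at -0.25 over 69 genes (camera adjusted p = 0.0025), which stood at -0.01 and was not called without control 1 (0.165), and which had -0.40 without control 3 and -0.15 without fed 1. Among transcription factor families, ZIM factors had a median of 1.57 over 30 genes and AP2-EREBP factors 0.71 over 88 genes (camera adjusted p of 2.00e-17 and 4.05e-10). The AP2-EREBP median was 1.20 without control 1. WRKY, NAC and bHLH factors were called higher too, with medians of 0.74, 0.41 and 0.17. The NAC call was lost without control 1 (median 0.37) and the bHLH call without control 3 (median 0.21). FAR1-like factors alone were called lower, at -0.35 over 14 genes (camera adjusted p = 0.0253). This call was lost without control 3 (median -0.23) and without fed 3 (median -0.32). With an estimated correlation each of these families had an adjusted p of 0.695 by camera.

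Control 3 lay over 8-fold below the lowest of the other 3 libraries at 361 of 16360 protein-coding loci. A lower depth is argued against, since fed 1, with the lowest total, was that far below the others at 15 loci. Fewer dividing cells are argued against as well: over 71 dividing-cell genes the log2 ratio of control 3 to the lowest other library had a median of 0.15 (SD 0.775) and a lowest value of -2.08, where an 8-fold fall is -3. A sample with less of the leaf part that is still building cell walls stays open: the cell wall organization term had an odds ratio of 8.34 among these loci, but it was picked from them. Of the lists fixed before the data were examined, terpene synthesis had 5 of 21 genes among them (odds ratio 14.02, adjusted p = 0.0017) and epidermis and cuticle 6 of 51 (5.99, adjusted p = 0.00949), while the cytosolic ribosome had 0 of 274 (odds ratio 0, adjusted p = 0.0387). The terpene and epidermis medians were 2.24 and 1.64 without control 1, where control 3 is the only control. Without control 3 they were 0.08 and -0.04.

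The test of lncRNA transcripts left out each transcript's own spread. It called MSTRG.17681.1, at 4404 FPKM in control 1 and 0 in the other libraries (limma adjusted p = 1.19e-18). It also called MSTRG.4209.1, at 7.07 and 2.18 FPKM in controls and 333 and 4.66 FPKM in fed 1 and fed 3 (limma adjusted p = 6.15e-11). How far the other calls rest on this stays open. With 1 prior spread for all transcripts (trend=FALSE) 0 were called, but in simulated data that setting found 0 of 66 transcripts shifted by 6 on the log2 scale. The fit with the trend found 0 of 66 there as well, though it called 14 higher and 11 lower in the data. The simulated data thus did not reproduce that fit and cannot show what either setting is able to find here. The loss is left undecided. Reads of 1 locus divided differently among its assembled transcripts stay open too for the calls as a whole. Called transcripts lay at loci with several transcripts more often than other tested ones (odds ratio 17.9, Fisher's exact test p = 2.01e-09), though transcripts of 1 locus are not independent. Of 11 called transcripts at loci with several transcripts, 5 were at loci whose total did not part the groups the same way. MSTRG.17681.1, MSTRG.17681.11 and MSTRG.17681.6 are not among these 5, because their locus total was lower in fed leaves too. Yet every called transcript of that locus was seen in 1 library alone. MSTRG.17681.11 was at 3491 FPKM in control 3, MSTRG.17681.10 at 280 FPKM in fed 1 and MSTRG.17681.7 at 1052 FPKM in fed 3. At this locus the division among transcripts thus differed between libraries, also within a group.

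The transcript antisense to lipoxygenase1 spanned 144313 bases with 255 in exons, starting within another lipoxygenase gene, Zm00001d042540. Reads of the lipoxygenase genes counted for it in proportion stay open: at the fed ratio control 1 would have 41.5 estimated counts and had 0. Control 3 would have 0.608, too few to decide, so the evidence against this explanation rests on 1 library. The fed libraries had similar ratios of 0.605% and 0.522%, but these set the expectation and are no separate evidence. A junction that joins neighbouring copies of a gene family may have produced it. Among the antisense transcripts 5.39% start in 1 coding locus and end in another. Whether those loci belong to the same family was not checked, so this share does not bear on the explanation. The strand of the libraries is not stated either, so a joining junction stays open.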
